A study of Mus musculus with 8 samples.

How the data were processed

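Gene expression was measured on 8 Affymetrix arrays, each hybridised with RNA of activated mouse CD4 T cells. Splenic cells came from wild-type (WT) mice or from mice lacking IFN-γ receptor 1 (KO). They were stimulated through CD3 and CD28 for 15 h and received db-cAMP or vehicle during the last 3 h. The 4 groups held 2 arrays each, which the titles call biological replicates. The sources used here do not say whether the replicates came from separate mice or cultures, so p-values measure only the spread between these samples. Group and replicate number were taken from the sample titles. The titles, the source names and the genotype entries put 4 arrays in the KO groups, whereas their free-text descriptions call the cells WT, and the first 3 were followed.

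The deposited values are linear signal intensity per probe set, 1 column per array. MAS5 made them, per the submitters' processing notes, and its version and settings are not given in the sources used here. Biotin-labelled cRNA was prepared with a 3-prime in vitro transcription kit, per the labels' protocols. The middle 96 percent of the values had a mean close to 499.8 in each column, so the intensity values had been scaled per array before they were deposited. No log and no centring had been applied, and the lowest intensity among the deposited values was 0.061. Scaling of this kind sets every array to the same mean, so a change in total mRNA per cell is not measured. Detection calls were not used here. Median signals per array ran from 56.2 to 70.5 and the 75th percentiles from 318 to 358. Arrays have no read depth, and their number limits the precision.

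Of 45101 probe sets, 64 were controls. In the platform annotation 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none, and genes were named only from the first kind. The Entrez identifiers of 34741 probe sets were found in a RefSeq table of assembly GRCm38.p6, used here for names and gene order only, and 0 symbols changed. The named probe sets covered 18193 genes. For each gene the probe set with the highest mean log2 value over the 8 arrays was used. Values were transformed as log2(value + 5.48), where the offset is the 10th percentile of all values, so fold changes of dim genes are understated. Genes above their array's median in at least 2 arrays were kept, which left 12091 genes tested and set aside 6102. No further scaling between arrays was applied. Some members of the gene lists were not analysed here.

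Differences were tested with limma (lmFit, then eBayes with an intensity trend) in R, with 1 term per group over all 8 arrays, 4 residual degrees of freedom and a median of 9 prior degrees of freedom. The versions were R 4.3.3 and limma 3.58.1, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. A gene counts as changed when its Benjamini-Hochberg adjusted p is under 0.05, and every adjusted p of a gene is limma's. The comparisons were db-cAMP against vehicle in WT, in KO and as the mean of both, KO against WT under each treatment, and the interaction, which is the KO effect minus the WT effect. Errors of log2 changes are standard errors of the fit, and group means are given with the SD of 2 arrays.

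Before the data were examined, 25 gene lists were fixed. These were cAMP and CREB target genes, cAMP signalling components, interferon-gamma induced genes, type I interferon induced genes, Th1, Th2, Th17 and regulatory T cell genes, T cell activation genes, quiescence and homing genes, cytokine receptor genes, JAK-STAT feedback and STAT5 target genes, cell cycle, ribosome biogenesis, glycolysis, cholesterol synthesis, unfolded protein and integrated stress response, and apoptosis genes, markers of B cells, CD8 T cells, NK cells, macrophages and neutrophils, dendritic cells, and erythroid cells and platelets, and T cell identity genes. Each list was tested with camera in limma, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 25 lists of a comparison. Named genes followed a rule also fixed then. It took the 8 largest rises and falls among changed genes (5 for KO against WT under db-cAMP, the interaction and the mean), up to 4 changed members of each list, and a set of interferon, cytokine and cAMP genes whatever their values. The text names a part of these and gives some of them in other comparisons too. Genes outside the rule are marked as chosen after their values were seen.

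The fit was tested on simulated data for db-cAMP against vehicle in WT, with the real means and the fit's moderated spreads of 12091 genes in 5 runs. It recovered 40% of genes changed 1.5-fold, 65.4% of those changed 2-fold and 80.9% of those changed 4-fold. Of 665 calls 45 (6.77%) were false, and 0 genes were called in the unchanged KO groups. Camera with the preset correlation found the 5 planted lists and 0 lists without a change. Simulated errors were independent between genes, so correlation within a list was not tested. The moderated spreads had already been drawn toward the trend by the fit under test, so the simulation may favour it. Changed genes numbered 335, 335 and 330 at these folds over the 5 runs, far fewer than the 4233 called in the real comparison.

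Alternatives fixed before the data were examined were quantile normalization, an equal 75th percentile, no offset, an offset at the median, no filter, a filter at the 75th percentile, eBayes without the intensity trend, every probe set, the mean of a gene's probe sets, a block for the replicate number, only the 4 arrays of a comparison, and leaving out each array. An interaction with the WT effect scaled down and a scaling to an equal median of the T cell identity genes were added after seeing the data.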

Results

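Transcripts were measured in activated CD4 helper T cells of mouse spleen with and without db-cAMP (dibutyryl cyclic AMP), a membrane-permeable analogue of the second messenger cyclic AMP that activates protein kinase A. The cells were WT or lacked the ligand-binding chain of the IFN-γ receptor, which T cells need to sense IFN-γ. There were 4 groups of 2 arrays, WT with vehicle, WT with db-cAMP, KO with vehicle and KO with db-cAMP. The design asks what cAMP does to gene expression in activated T cells and which part of it depends on the IFN-γ receptor. Replicate arrays correlated at 0.961 to 0.977 across the 12091 genes tested, which are not independent replicates, and held at most 1 identical value. Values are scaled linear signals, and the small number of arrays limits their precision.

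The targeted gene, Ifngr1, gave a signal of 889 ± 22.4 (SD, n = 2) in WT cells with vehicle and 7760 ± 624 with db-cAMP. In KO cells it gave 408 ± 43.5 and 1164 ± 153. Ifngr1 was lower in KO cells by a log2 change of -1.12 ± 0.12 under vehicle (adjusted p = 4.1e-05) and of -2.74 ± 0.12 under db-cAMP (adjusted p = 2.97e-09). Where this probe set lies relative to the disrupted part of the gene is not given in the sources used here, so its signal checks nothing about the genotype. The descriptions of the 4 KO arrays call the cells WT, against their titles and genotype entries. Genes that IFN-γ induces bear on this. Gbp2, a guanylate-binding protein, stood at 7532 ± 808 in WT and 432 ± 68.2 in KO cells under vehicle (SD, n = 2), and Iigp1, an immunity-related GTPase, at 2156 and 96.2.

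**Figure D1:**
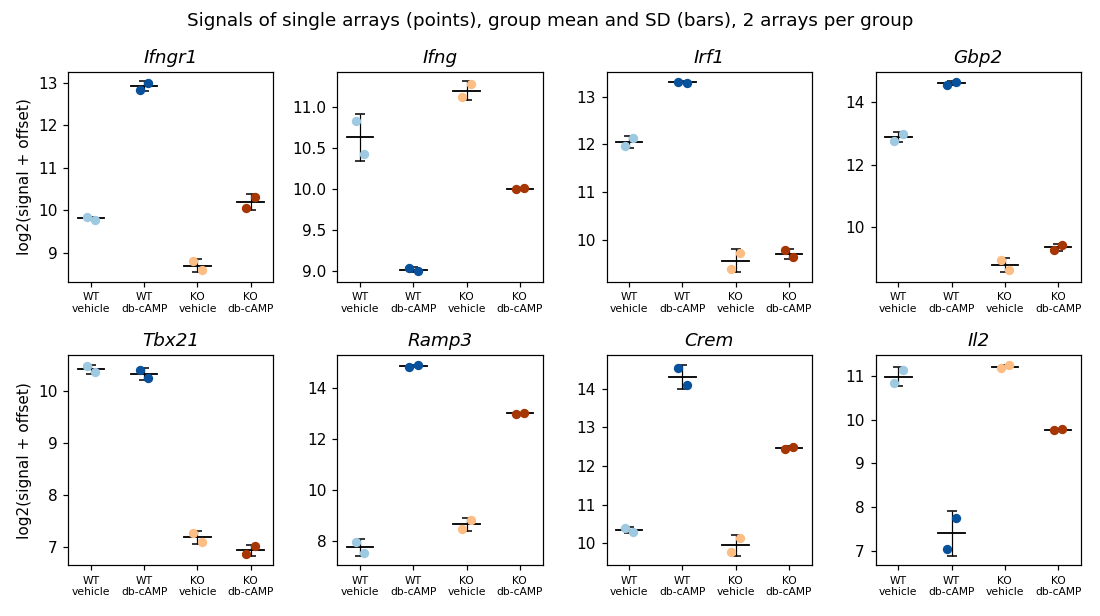
Log2 of signal plus offset (vertical axis) of 8 genes in the 4 groups, with a point per array, a line at the group mean and bars for the SD of 2 arrays. The mean Crem signal rose with db-cAMP from 1289 to 20600 in WT and from 991 to 5654 in KO cells, whereas Irf1 stood at 4246 and 10100 in WT and at 752 and 828 in KO cells.

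In WT cells, db-cAMP raised cAMP and CREB target genes, interferon-gamma induced genes, both chains of the IFN-γ receptor, and quiescence and homing genes, and lowered T cell activation genes and ribosome biogenesis genes as well as Ifng and Il2. The largest rise was that of Ramp3, a partner protein of calcitonin-family receptors, from 215 ± 48.2 to 30150 ± 1040 (SD, n = 2), a 139-fold change (log2 7.12 ± 0.14, adjusted p = 2.91e-12). Cxcr4, the chemokine receptor for CXCL12, rose 21.4-fold from 172 to 3778. Tent5a rose by 5.04 ± 0.3 and Adh1, an alcohol dehydrogenase, by 4.19 ± 0.11 on the log2 scale. Il2, the T cell growth factor, fell from 2033 ± 308 to 168 ± 59.3 (log2 -3.59 ± 0.18, adjusted p = 6.62e-09). Hivep3, a zinc finger transcription factor, changed by -4.35 ± 0.1 and Tnfsf14, the TNF-family ligand LIGHT, by -3.73 ± 0.33.

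Of 27 measured cAMP and CREB target genes, 19 rose, 2 fell and 6 did not pass the test in WT cells, and 20 rose and 2 fell when adjusted over the list alone (camera adjusted p = 7.43e-09, and adjusted p = 0.0442 with an estimated correlation). Crem, which encodes the cAMP-inducible repressor ICER, rose by 3.98 ± 0.14. The cAMP-degrading phosphodiesterases Pde4d, Pde4b and Pde3b rose by 3.74, 2.26 and 1.54. Nr4a2, an orphan nuclear receptor, rose by 1.77 ± 0.07, whereas its relative Nr4a1 stood at 0.07 ± 0.11 (adjusted p = 0.688). The members that fell, named after their values were seen, were Id3 at -2.23 and Rgs1 at -1.38. Among 23 cAMP signalling components 6 rose and 6 fell, also when adjusted over the list alone (adjusted p = 0.749). They included Ptger2, a prostaglandin E2 receptor that signals through cAMP, at -2.8 ± 0.1, and the adenylyl cyclase Adcy6 at 1.5 ± 0.19.

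IFN-γ itself and the genes it induces went opposite ways in WT cells. Ifng fell from 1591 ± 314 to 513 ± 11.9 (SD, n = 2; log2 -1.61 ± 0.13, adjusted p = 3.6e-07), while Ifngr1 rose by 3.12 ± 0.12 and Ifngr2, the second receptor chain, by 2.36 ± 0.15. Of 30 interferon-gamma induced genes, 22 rose, 1 fell and 7 did not pass, with the same 22 and 1 when adjusted over the list alone (adjusted p = 9.14e-07, and adjusted p = 0.0442 with an estimated correlation). Cxcl10, a chemokine, rose by 2.8 ± 0.28, the GTPase Igtp by 2.08 ± 0.11, Gbp2 by 1.73 ± 0.11 and the transcription factor Irf1 by 1.25 ± 0.11. The member that fell, named after its value was seen, was Cd274, which encodes PD-L1, at -0.32 ± 0.1. Among 21 type I interferon induced genes 8 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.0365, but adjusted p = 0.201 with an estimated correlation). Ifit1, an RNA-binding antiviral protein, rose by 3.68 ± 0.58 and Usp18, a negative regulator of interferon signalling, by 3.15 ± 0.28, while Ifih1, named after its value was seen, stood at -0.57. Without WT db-cAMP replicate 1 this list was not called (adjusted p = 0.0894).

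T cell activation and ribosome biogenesis genes fell in WT cells. Of 24 T cell activation genes 3 rose and 15 fell, and 4 rose and 15 fell when adjusted over the list alone (adjusted p = 0.000149, and adjusted p = 0.049 with an estimated correlation). Egr2 and Egr3, transcription factors induced by the T cell receptor, stood at -2.91 ± 0.14 and -2.96 ± 0.1, and Myc, a driver of growth, at -1.98 ± 0.07. The members that rose, named after their values were seen, were Tnfrsf9, Icos and Rel at 0.88, 0.82 and 0.81. Of 28 ribosome biogenesis genes 25 fell and 0 rose, and 26 fell when adjusted over the list alone (adjusted p = 8.59e-14, and adjusted p = 0.0253 with an estimated correlation). Gnl3, a nucleolar GTP-binding protein, stood at -2.02 ± 0.08 and Polr1b, a subunit of RNA polymerase I, at -1.91 ± 0.15. Of 20 quiescence and homing genes 15 rose and 3 fell, and 15 rose and 4 fell when adjusted over the list alone (adjusted p = 1.88e-05, and adjusted p = 0.049 with an estimated correlation). Tsc22d3, a leucine zipper protein also known as GILZ, rose by 2.28, the homing receptor Ccr7 by 1.92, the chromatin organiser Satb1 by 1.94 and Klf2, which controls T cell trafficking, by 1.84. The falls in this list, named after their values were seen, were Slfn2, Foxp1 and Bach2 at -1.4, -1.03 and -0.57. Beside these and the other gene groups, control signals moved with db-cAMP in WT cells. Poly-A controls stood at 830 and 959 on the vehicle arrays and at 1044 and 1221 with db-cAMP, 18S rRNA probe sets at 26560 and 23380 against 35580 and 34500, and the ratio of 3-prime to 5-prime 18S signals at 0.386 and 0.353 against 0.441 and 0.41. Hybridization controls and the Gapdh and Actb ratios, a sign of RNA quality and labelling, overlapped between the treatments.

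Helper subset genes moved both ways in WT cells. Of 21 Th1 genes 5 rose and 8 fell (7 and 8 adjusted over the list alone; adjusted p = 0.927), with a median of 0.28 while the test leaned lower. The cytokines Lta, Ccl3 and Tnf stood at -2.8, -2.72 and -2.66, while Stat4, which transmits the IL-12 signal, rose from 1529 to 8471 (log2 2.47 ± 0.08). Tbx21, which encodes the Th1 regulator T-bet, stood at -0.09 ± 0.16 (adjusted p = 0.696). Of the IL-12 receptor chains, Il12rb1 fell by 1.45 on the log2 scale and Il12rb2 stood at 2.12 ± 0.9 (adjusted p = 0.0884). Th2 genes showed 2 rises and 2 falls among 10 (the same adjusted over the list alone; adjusted p = 0.749), with Gata3, the Th2 regulator, at 1.28 ± 0.14. Th17 genes showed 2 rises and 4 falls among 8 (the same adjusted over the list alone; adjusted p = 0.738), with Rora at 1.43 ± 0.18 and Il17a at 0.09 ± 0.19, which did not pass. Among 13 regulatory T cell genes 4 rose and 3 fell (4 and 4 adjusted over the list alone; adjusted p = 0.927), and Foxp3, their defining factor, stood at 0.3 ± 0.24 (adjusted p = 0.379).

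Cytokine receptor genes showed 11 rises and 6 falls among 24 in WT cells (13 and 7 adjusted over the list alone; adjusted p = 0.0777). JAK-STAT feedback and STAT5 target genes showed 12 rises and 4 falls among 23 (the same adjusted over the list alone; adjusted p = 0.0195, but adjusted p = 0.266 with an estimated correlation), led by the feedback inhibitor Socs3 at 2.68 ± 0.15 and by Stat3 at 2.39 ± 0.1. Its falls, named after their values were seen, were Ptpn6, Pim3, Socs2 and Pim2 at -1.57, -1.2, -0.9 and -0.24. Among 31 cell cycle genes 2 rose and 5 fell (the same adjusted over the list alone; adjusted p = 0.366), with the cyclin-dependent kinase inhibitor Cdkn1b at 1.93 ± 0.13. Glycolysis genes showed 5 rises and 4 falls among 17 (6 and 5 adjusted over the list alone; adjusted p = 0.969), with hexokinase Hk2 at -2.07 ± 0.13 and Hif1a, a regulator of glycolysis, at 1.29 ± 0.08. Cholesterol synthesis genes showed 1 rise and 8 falls among 22 (2 and 8 adjusted over the list alone; adjusted p = 0.124). The stress response list showed 4 rises and 8 falls among 21 (6 and 8 adjusted over the list alone; adjusted p = 0.969), and apoptosis genes 5 rises and 4 falls among 17 (the same adjusted over the list alone; adjusted p = 0.969). T cell identity genes showed 4 rises and 4 falls among 12 (the same adjusted over the list alone; adjusted p = 0.969). The median and the mean log2 change differed in sign for regulatory T cell genes (0.07 and -0.03) and apoptosis genes (0.18 and -0.02), and the stress response test leaned lower with a median of 0.02.

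Few markers of other cells passed the test in WT cells, and each count was the same when adjusted over the list alone. Of 11 B cell markers 1 fell (adjusted p = 0.791), the immunoglobulin gene Ighm at -1.04 ± 0.1, which stood at -0.06 (adjusted p = 0.876) as the mean of its probe sets. Of 5 NK cell markers 1 rose (adjusted p = 0.36), Klrd1 at 0.83 ± 0.15. In limma 0 of 2 CD8 T cell, 9 macrophage and neutrophil, 8 dendritic cell, and 5 erythroid and platelet markers passed (adjusted p = 0.466, 0.969, 0.969 and 0.791), and 0, 0, 2 and 1 of them had an unadjusted p under 0.05.

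In all, 4233 of 12091 genes passed for db-cAMP in WT cells, 1984 higher and 2249 lower, and of these 635 and 536 changed by 2-fold or more. Counting every probe set gave 6890 calls. Some small changes named above rested on single arrays or settings. Cd274 was not called without WT vehicle replicate 1 (adjusted p = 0.104) or WT db-cAMP replicate 1 (0.0877), nor Ifih1 without WT vehicle replicate 1 (0.0954) or WT db-cAMP replicate 2 (0.0928). Pim2 was lost without WT vehicle replicate 1 (0.0911) or 2 (0.134), WT db-cAMP replicate 1 (0.108) or 2 (0.0976), KO db-cAMP replicate 1 (0.0558) or 2 (0.0557), without the intensity trend (0.105), after quantile normalization (0.0591) and over every probe set (0.0555). Socs2 was lost without the trend (0.0664) and as the mean of its probe sets (0.0846).

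In KO cells db-cAMP moved fewer genes past the threshold, and the changes of cAMP targets, activation, quiescence and ribosome biogenesis genes kept the directions seen in WT cells, while most interferon-gamma induced genes did not pass. Ifngr1 rose by 1.5 ± 0.12 and Ifngr2 by 1.08 ± 0.15 on the log2 scale. Ramp3 again rose most, from 404 ± 75 to 8269 ± 64 (SD, n = 2; log2 4.35 ± 0.14, adjusted p = 1.65e-09), and Vps37b, an endosomal sorting protein, rose by 2.71 ± 0.11. Il2 fell from 2377 ± 69.9 to 868 ± 5.2 (log2 -1.45 ± 0.18, adjusted p = 0.000237) and Ifng from 2339 ± 184 to 1019 ± 5.95 (log2 -1.19 ± 0.13, adjusted p = 5.55e-05).

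Of 27 cAMP and CREB target genes 16 rose and 2 fell in KO cells, and 20 rose and 2 fell when adjusted over the list alone (adjusted p = 3.51e-12, and adjusted p = 0.0241 with an estimated correlation), with Pde4d at 2.66 ± 0.14, Crem at 2.52 ± 0.14 and Nr4a1 at 0.66 ± 0.11, against Id3 at -1.2 and Rgs1 at -0.66. Quiescence and homing genes showed 14 rises and 1 fall among 20 (15 and 2 adjusted over the list alone; adjusted p = 1.49e-10, and adjusted p = 0.0241 with an estimated correlation), with Cxcr4 at 2.64 ± 0.12 and Klf2 at 1.17 ± 0.1, against Slfn2 at -0.27. Activation genes showed 2 rises and 13 falls among 24 (the same adjusted over the list alone; adjusted p = 9.2e-07, and adjusted p = 0.0269 with an estimated correlation), with Tnfsf14 at -2.32 ± 0.33 and Egr2 at -1.22 ± 0.14, against Tnfrsf9 and Icos, each at 0.49. These genes that moved against their list were named after their values were seen. Of 28 ribosome biogenesis genes 17 fell and 0 rose, and 22 fell when adjusted over the list alone (adjusted p = 3.51e-12, and adjusted p = 0.0241 with an estimated correlation), with Rrp9 at -0.8 and Ppan at -0.53. Cytokine receptor genes showed 9 rises and 2 falls among 24 (11 and 2 adjusted over the list alone; adjusted p = 0.0013, but adjusted p = 0.11 with an estimated correlation), the falls being Il6ra at -0.7 and, named after its value was seen, Il15ra at -0.63. Of 22 cholesterol synthesis genes 1 fell, Cyp51 at -0.36 ± 0.08, and 5 fell when adjusted over the list alone (adjusted p = 0.00226, but adjusted p = 0.0951 with an estimated correlation). The JAK-STAT list (adjusted p = 0.0246, but adjusted p = 0.273 with an estimated correlation) and T cell identity genes (adjusted p = 0.0164, but adjusted p = 0.315 with an estimated correlation) stood higher with 5 rises and 1 fall, Ptpn6 at -0.93, named after its value was seen, and with 4 rises and 0 falls (8 and 2, and 5 and 0, adjusted over the list alone). The first was not called without KO db-cAMP replicate 2 (adjusted p = 0.109), KO vehicle replicate 1 (0.0537) or the WT arrays (0.0651). T cell identity was not called without KO vehicle replicate 1 (adjusted p = 0.132) or KO db-cAMP replicate 1 (0.0602), or with the mean of probe sets (0.116). Beside these groups, too, most control signals moved with db-cAMP without overlap. In KO cells poly-A controls stood at 2781 and 2476 on the vehicle arrays against 3496 and 2931, 18S rRNA probe sets at 23710 and 25880 against 37920 and 30460, hybridization controls at 5992 and 5856 against 6592 and 6086, and the 3-prime to 5-prime ratios at 0.522 and 0.513 against 0.623 and 0.548 for 18S rRNA and at 0.779 and 0.797 against 0.85 and 0.817 for Gapdh. The Actb ratio overlapped, at 1.35 and 1.4 against 1.44 and 1.34. Of 5 NK cell markers 1 rose (camera adjusted p = 0.396 for the list), and in the other lists of cell markers 0 passed.

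Of 30 interferon-gamma induced genes 4 rose and 3 fell in KO cells, and 7 rose and 3 fell when adjusted over the list alone (adjusted p = 0.57). Irgm2, a GTPase, rose by 0.77 ± 0.17 and, named after their values were seen, Irf9 rose by 0.64, Gbp2 by 0.57 ± 0.11 and Gbp7 by 0.45. Cd274 stood at -1.27 ± 0.1, Irf8, a transcription factor, at -0.85 ± 0.09 and Pml, named after its value was seen, at -1.02. Igtp at 0.16 ± 0.11 (adjusted p = 0.48) and Irf1 at 0.15 ± 0.11 (adjusted p = 0.537) did not pass. In the Th1 and Th17 lists, which were not called in KO cells (adjusted p = 0.0582 and 0.771), Stat4 rose by 1.7 ± 0.08 and Rora by 1.88 ± 0.18, and Tnf stood at -2.06 ± 0.28.

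The KO comparison called 1013 genes, 568 higher and 445 lower, of which 119 and 23 changed by 2-fold or more. With an equal 75th percentile the split was 449 higher and 585 lower. Without the intensity trend 188 genes passed, 144 higher and 44 lower, and Il2 (adjusted p = 0.0676), Tnf (0.0843), Egr2 (0.0522), Nr4a1 (0.128), Rrp9 (0.0575), Ppan (0.082), Irgm2 (0.175) and Cyp51 (0.134) no longer passed, nor did Slfn2 (0.25), Tnfrsf9 (0.0949), Icos (0.1), Il6ra (0.113), Il15ra (0.104), Irf9 (0.104), Gbp2 (0.153), Gbp7 (0.0786) and Pml (0.0758). With the mean of each gene's probe sets 598 passed, and Tnfsf14 (adjusted p = 0.293), Rora (0.0752), Ifngr2 (0.106), Cyp51 (0.242), Slfn2 (0.0517), Gbp7 (0.299) and Pml (0.655) did not. Without a filter Slfn2 (adjusted p = 0.0656), Il15ra (0.0511) and Pml (0.0581) were lost, and with only the 4 KO arrays Irgm2 (0.065) and Gbp7 (0.109). Calls lost without KO vehicle replicate 1 were Il6ra (adjusted p = 0.114), Il15ra (0.0699) and Pml (0.18), and without KO vehicle replicate 2 Irgm2 (0.141), Cyp51 (0.133), Slfn2 (0.296), Il15ra (0.211), Gbp2 (0.0842), Gbp7 (0.0923) and Pml (0.0558). Those lost without KO db-cAMP replicate 1 were Irgm2 (0.145), Cyp51 (0.152), Slfn2 (0.165), Il6ra (0.115), Il15ra (0.112), Irf9 (0.0835), Gbp7 (0.0901) and Pml (0.195), and without KO db-cAMP replicate 2 Cyp51 (0.0578), Slfn2 (0.226), Il15ra (0.188), Gbp2 (0.0757), Gbp7 (0.104) and Pml (0.0626). Slfn2 was also lost without WT vehicle replicate 1 (0.0525) or 2 (0.0529) and over every probe set (0.0695). Counts were 446 without KO db-cAMP replicate 2, 460 without KO vehicle replicate 2 and 479 without KO db-cAMP replicate 1.

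The db-cAMP effects in the 2 genotypes, which share no arrays, pointed the same way at most genes called in either and were mostly smaller in KO cells. In a count chosen after seeing the data, 984 of the 1013 genes called in KO cells (97.1%) had the same sign in WT cells, against 50.1% for independent signs, and 868 had a larger change there. Of the 4233 genes called in WT cells 3768 (89%) had the same sign in KO cells, against 50%. Over all genes the log2 changes correlated across genes, which are not independent replicates, at r = 0.396 (Spearman rho 0.447), and at 0.194 without a filter, 0.619 with an offset at the median and 0.815 with a filter at the 75th percentile. The slope of KO on WT effects was 0.438 over the 4032 genes called for the mean of both genotypes, 0.511 over those called in KO and 0.356 over those called in WT cells. In both genotypes 519 genes rose, against 93.2 for independent lists, and 411 fell, against 82.8, while 7 were called in opposite directions. Each of these 7 lost its KO call without the intensity trend (adjusted p from 0.119 to 0.212). The mean effect rose at 1922 and fell at 2110 genes, with Ramp3 at 5.73 ± 0.1 and Hivep3 at -2.74 ± 0.07. Ifngr1 stood at 2.31 ± 0.08 in this mean. The cAMP and CREB target, interferon-gamma induced, activation, quiescence and ribosome biogenesis lists were called for it in their WT directions (adjusted p = 2.14e-10, 0.000155, 3.56e-05, 3.68e-06 and 2.75e-14; with an estimated correlation adjusted p = 0.0454, 0.0454, 0.0454, 0.0454 and 0.0236).

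**Figure D2:**
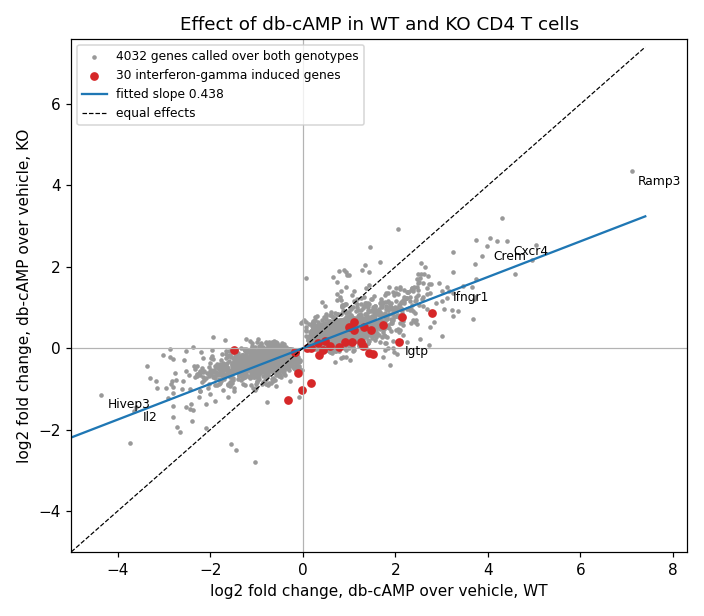
Log2 change after db-cAMP in KO cells (vertical axis) against WT cells (horizontal axis), a grey point for each of the 4032 genes called for the mean of both genotypes and a red point for each of 30 interferon-gamma induced genes. The solid line has the fitted slope of 0.438 and the dashed line marks equal effects, and Ramp3 lies at 7.12 in WT and 4.35 in KO cells.

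The interaction tested that difference gene by gene, where a negative value means a lower effect in KO cells. The effect on Ifngr1 was lower in KO cells by -1.62 ± 0.16 (adjusted p = 4.22e-05). Of 30 interferon-gamma induced genes 17 had a lower and 0 a higher effect in KO cells, and 21 a lower one when adjusted over the list alone (adjusted p = 2.51e-11, and adjusted p = 0.0166 with an estimated correlation). Igtp stood at -1.92 ± 0.16, Cxcl10 at -1.93 ± 0.39 and Irf1 at -1.11 ± 0.16. Of 28 ribosome biogenesis genes 20 had a higher, that is less negative, effect (22 higher and 1 lower adjusted over the list alone; adjusted p = 5.24e-13, and adjusted p = 0.0166 with an estimated correlation), with Gnl3 at 1.55 ± 0.12. The cAMP and CREB targets (3 higher, 10 lower, or 3 and 13 adjusted over the list alone; adjusted p = 0.000199, but adjusted p = 0.0922 with an estimated correlation) included Crem at -1.46 ± 0.19, against Nr4a1 at 0.59, Rgs1 at 0.72 and Id3 at 1.04. Activation genes (12 higher, 2 lower, or 14 and 3 adjusted over the list alone; adjusted p = 0.00167, but adjusted p = 0.0922 with an estimated correlation) included Il2 at 2.15 ± 0.26, against Tnfrsf9 at -0.39 and Rel at -0.66. For type I interferon induced genes (0 higher, 6 lower, or 0 and 7 adjusted over the list alone) and quiescence genes (3 and 8, or 3 and 11 adjusted over the list alone) the adjusted p was 0.00256, but adjusted p = 0.0922 with an estimated correlation. The higher quiescence genes were Slfn2, Foxp1 and Bach2 at 1.13, 0.81 and 0.74, and all these members against their list except Nr4a1 were named after their values were seen. Ifng stood at 0.42 ± 0.18 (adjusted p = 0.172), so its fall was not shown to differ between genotypes. The test called 1425 genes, 810 with a higher and 615 with a lower effect in KO cells. With the WT effect first multiplied by the common slope of 0.438, an alternative chosen after seeing the data, it called 30, 21 higher and 9 lower. Without the intensity trend it called 261, and Il2 (adjusted p = 0.0539), Crem (0.0674), Irf1 (0.0669), Cxcl10 (0.0884), Nr4a1 (0.222), Rgs1 (0.0676), Id3 (0.0669), Tnfrsf9 (0.198), Rel (0.146), Foxp1 (0.0711) and Bach2 (0.0669) did not pass. Tnfrsf9 was lost without every array except WT vehicle replicate 2 and WT db-cAMP replicate 1 (adjusted p up to 0.162, without KO db-cAMP replicate 2), after quantile normalization (0.0946), without a filter (0.0503), over every probe set (0.0633) and as the mean of its probe sets (0.334). Nr4a1 was lost without every array except WT vehicle replicate 1 and WT db-cAMP replicate 1 (up to 0.116, without KO vehicle replicate 2) and as the mean of its probe sets (0.0532). Rel was lost without WT vehicle replicate 2 (0.0881), WT db-cAMP replicate 1 (0.0754), KO vehicle replicate 2 (0.102) and KO db-cAMP replicate 1 (0.0712) or 2 (0.081). Counts were 848 with the mean of probe sets, 891 and 895 without KO db-cAMP replicate 1 or 2.

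**Figure D3:**
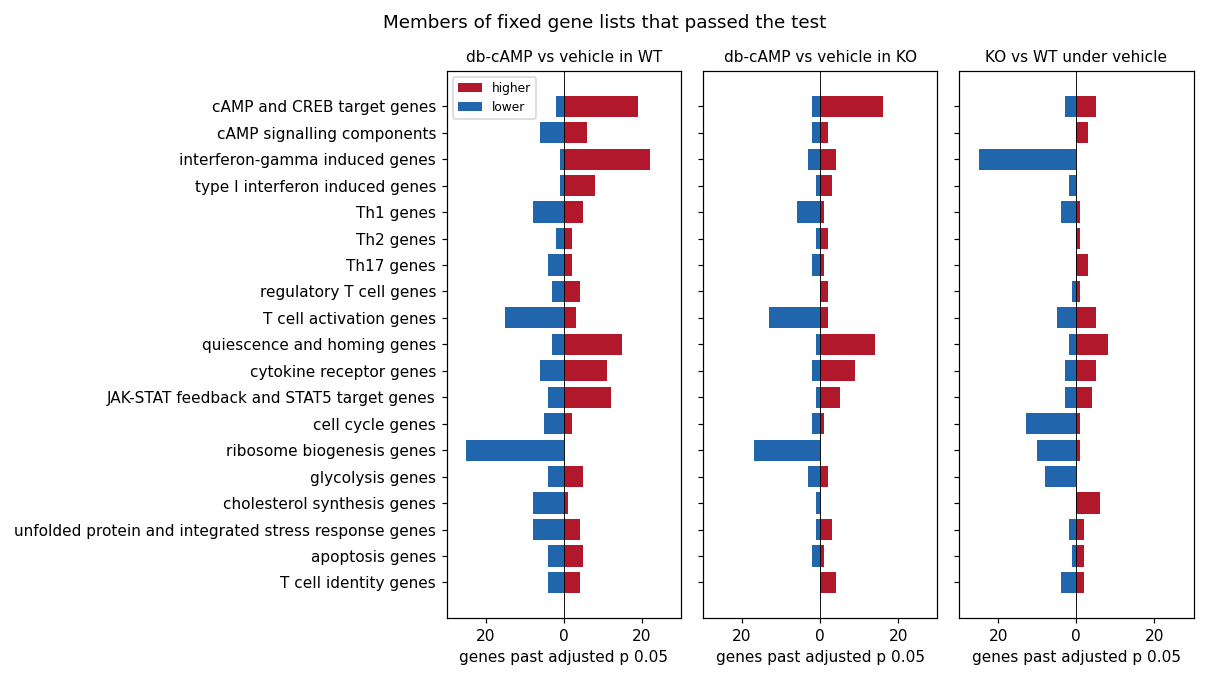
Number of members of each gene list that passed the test (horizontal axis), higher to the right in red and lower to the left in blue, for db-cAMP in WT, db-cAMP in KO and KO against WT under vehicle. Of 30 interferon-gamma induced genes 22 rose and 1 fell in WT cells, 4 rose and 3 fell in KO cells, and 25 were lower in KO than in WT cells under vehicle.

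Without db-cAMP, KO cells expressed fewer IFN-γ-induced and cell cycle transcripts than WT cells and more of 3 Th17-associated ones. Ifngr1 was lower by -1.12 ± 0.12, on a probe set that checks nothing about the genotype. Of 30 interferon-gamma induced genes 25 were lower and 0 higher, the same when adjusted over the list alone (adjusted p = 8.47e-29, and adjusted p = 0.00505 with an estimated correlation). Iigp1 stood at -4.42 ± 0.14, Gbp2 at -4.11 ± 0.11 and Irf1 at -2.5 ± 0.11. Tbx21 fell from 1357 ± 80.4 in WT to 141 ± 12.2 in KO cells (SD, n = 2; log2 -3.22 ± 0.16, adjusted p = 2.61e-08). Ifng was higher in KO cells, 2339 ± 184 against 1591 ± 314 (log2 0.57 ± 0.13, adjusted p = 0.0113). The largest rise was that of Erdr1, from 144 to 6708 (log2 5.67 ± 0.35), and Tnfsf8, the CD30 ligand, stood at 2.49 ± 0.13.

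Of 31 cell cycle genes 13 were lower and 1 higher in KO cells under vehicle, and 16 and 1 when adjusted over the list alone (adjusted p = 8.37e-08, and adjusted p = 0.0339 with an estimated correlation). Top2a, a topoisomerase of dividing cells, stood at -1.3 ± 0.12, Cdk1, the mitotic kinase, at -1.17 ± 0.25 and Rrm2, which makes deoxynucleotides, at -1.1 ± 0.12. The higher one, named after its value was seen, was the cell cycle inhibitor Cdkn1a at 0.71. Of 17 glycolysis genes 8 were lower and 0 higher, and 9 lower adjusted over the list alone (adjusted p = 0.000431, but adjusted p = 0.112 with an estimated correlation), with Tpi1, a glycolytic enzyme, at -0.82 ± 0.07. Cholesterol synthesis genes showed 6 higher and 0 lower of 22 (7 and 0 adjusted over the list alone; adjusted p = 0.0016, but adjusted p = 0.112 with an estimated correlation). Of 8 Th17 genes 3 were higher, the same adjusted over the list alone (adjusted p = 0.0193, but adjusted p = 0.16 with an estimated correlation), namely Ccr6 at 1.56 ± 0.22, the cytokine Il17a at 0.92 ± 0.19 and Il6ra at 0.72 ± 0.15. Of 20 quiescence genes 8 were higher and 2 lower (10 and 4 adjusted over the list alone; adjusted p = 0.0193, but adjusted p = 0.16 with an estimated correlation), and 4 and 4 with an equal 75th percentile. The lower ones, named after their values were seen, were Klf2 at -0.35 and Slfn2 at -0.37. Of 28 ribosome biogenesis genes 1 was higher and 10 lower (the same adjusted over the list alone; adjusted p = 0.0361, but adjusted p = 0.161 with an estimated correlation), and 1 and 4 after quantile normalization (adjusted p = 0.901). The higher one, named after its value was seen, was Nop58 at 0.39. Of 21 type I interferon induced genes 2 were lower, Zbp1 at -2.43 ± 0.19 and Usp18 at -1.04 ± 0.28, the same adjusted over the list alone (adjusted p = 0.0153, but adjusted p = 0.158 with an estimated correlation).

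Beside these gene groups, several measures moved with the genotype. Poly-A control transcripts were 2.89-fold brighter on KO arrays (2898 ± 427 against 1004 ± 164, SD, n = 4 arrays), and hybridization controls stood at 6125 ± 321 against 9322 ± 1580. The ratio of 3-prime to 5-prime probe set signals also lay apart without overlap. It ran from 0.734 to 0.769 on WT and from 0.779 to 0.85 on KO arrays for Gapdh, from 1.46 to 1.72 and from 1.34 to 1.44 for Actb, and from 0.353 to 0.441 and from 0.513 to 0.623 for 18S rRNA. Under vehicle 1 of 2 CD8 markers was lower, Cd8b1 at -0.92 ± 0.21 (adjusted p = 0.0587 for the list), as were 2 of 8 dendritic cell markers, Ly6d and Cst3 at -1 ± 0.23 and -0.35 ± 0.09 (adjusted p = 0.132 for the list). Of 12 T cell identity genes 2 were higher and 4 lower, and 2 and 5 adjusted over the list alone (adjusted p = 0.152). The T cell receptor chain Cd247 stood at -0.76 ± 0.07, and the higher ones, named after their values were seen, were Cd28 at 0.3 and Cd6 at 0.26. This split was 3 and 2 after quantile normalization and 0 and 5 with an equal 75th percentile.

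**Figure D4:**
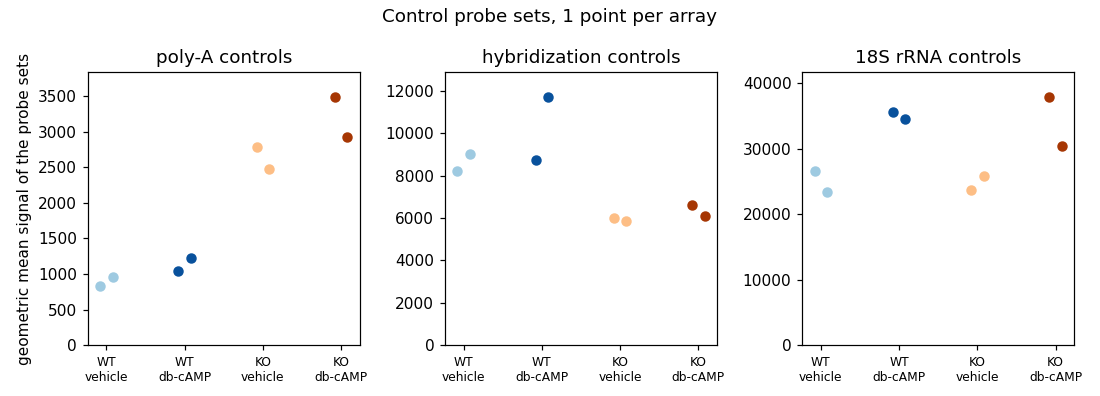
Geometric mean signal of poly-A, hybridization and 18S rRNA control probe sets (vertical axes) in the 4 groups, with a point per array. Poly-A controls lie between 830 and 1221 on the WT arrays and between 2476 and 3496 on the KO arrays.

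Under vehicle 1311 genes passed, 612 higher and 699 lower in KO cells, against 402 higher and 1173 lower with an equal 75th percentile. Without the intensity trend 251 passed, and Ifng (adjusted p = 0.138), Il17a (0.0501), Il6ra (0.0937), Cdk1 (0.128), Usp18 (0.184), Cst3 (0.176), Cdkn1a (0.0723), Klf2 (0.195), Slfn2 (0.13) and Nop58 (0.139) did not. Top2a stood at -0.74 (adjusted p = 0.121) as the mean of its probe sets. Calls lost without WT vehicle replicate 1 were Cdk1 (adjusted p = 0.0699), Cd8b1 (0.0611), Klf2 (0.176) and Cst3 (0.139), and without WT vehicle replicate 2 Ifng (0.114), Il6ra (0.0507), Usp18 (0.222), Cd8b1 (0.065), Ly6d (0.091), Klf2 (0.0944) and Cst3 (0.0677). Those lost without KO vehicle replicate 1 were Il17a (0.0918), Il6ra (0.105), Usp18 (0.223), Cd8b1 (0.0922), Ly6d (0.0756), Klf2 (0.0783), Slfn2 (0.0712) and Cst3 (0.207), and without KO vehicle replicate 2 Ifng (0.109), Cdk1 (0.102), Klf2 (0.213), Nop58 (0.0639) and Ly6d (0.0507). Klf2 was also lost without KO db-cAMP replicate 1 (0.0624) or 2 (0.0623), without a filter (0.0532), as the mean of its probe sets (0.0542), with only the vehicle arrays (0.0684) and with an equal T cell identity median (0.0564), and Usp18 without a filter (0.0536) and with only the vehicle arrays (0.094). Cd6 and Cd28 were lost without the trend (0.173 and 0.165), without WT vehicle replicate 1 (0.16 and 0.144), KO vehicle replicate 1 (0.052 and 0.099) or 2 (0.152 and 0.0594), with an equal 75th percentile (0.156 and 0.0935) and with an equal T cell identity median (0.0658 and 0.0654). Cd6 was also lost without WT vehicle replicate 2 (0.0504) and with only the vehicle arrays (0.0513), and Cd28 as the mean of its probe sets (0.703). Without WT vehicle replicate 1 the type I interferon, Th17, quiescence and ribosome lists were not called (adjusted p = 0.0917, 0.0754, 0.0917 and 0.0917). The ribosome list was also lost without KO vehicle replicate 1 (0.107), WT db-cAMP replicate 1 or 2 (0.0785 each) or KO db-cAMP replicate 1 or 2 (0.0552 each), without a filter (0.052), with only the vehicle arrays (0.12) and with the mean of probe sets (0.197), and with the Th17 list under a filter at the 75th percentile (0.0622 each). Counts were 815 and 806 without WT vehicle replicate 1 or 2, 617 and 775 without KO vehicle replicate 1 or 2, and 2733 over every probe set.

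With db-cAMP the gap in interferon-gamma induced genes was wider, and ribosome biogenesis genes were higher in KO than in WT cells. Ifngr1 was lower by -2.74 ± 0.12. Of 30 interferon-gamma induced genes 28 were lower and 0 higher, the same adjusted over the list alone (adjusted p = 5.23e-23, and adjusted p = 0.00789 with an estimated correlation), with Iigp1 at -5.67 ± 0.14, Gbp6 at -5.58 ± 0.19 and Irf1 at -3.6 ± 0.11. Tbx21 stood at -3.37 ± 0.16. Of 28 ribosome biogenesis genes 22 were higher and 3 lower, the same adjusted over the list alone (adjusted p = 6.98e-08, and adjusted p = 0.0394 with an estimated correlation), with Polr1b at 1.57 ± 0.15 and Gnl3 at 1.26 ± 0.08. The lower ones were the abundant nucleolar proteins Npm1 at -0.72 ± 0.09 and Ncl at -0.47 ± 0.08 and, named after its value was seen, Fbl at -0.4. After quantile normalization Npm1 stood at -0.02 (adjusted p = 0.874), Ncl at 0.06 (0.379) and Fbl at 0.01 (0.945), so the directions of Ncl and Fbl turn with the scaling and the call of Npm1 is lost. Il2 was higher in KO cells by 2.38 ± 0.18, Hivep3 by 3.53 ± 0.1 and Egr2 by 1.83 ± 0.14.

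Activation genes showed 14 higher and 2 lower of 24 in KO cells under db-cAMP (15 and 3 adjusted over the list alone; adjusted p = 8.22e-05, but adjusted p = 0.0527 with an estimated correlation), the lower ones, named after their values were seen, being Tnfrsf9 at -0.39 and Rel at -0.4. Type I interferon induced genes showed 9 lower of 21 (11 adjusted over the list alone; adjusted p = 1.55e-05, but adjusted p = 0.0527 with an estimated correlation), with Ifit1 at -3.53 ± 0.58. The cAMP and CREB targets showed 3 higher and 13 lower of 27 (the same adjusted over the list alone; adjusted p = 0.00303, but adjusted p = 0.129 with an estimated correlation), the higher ones being Nr4a1 at 1.13 and, named after their values were seen, Id3 at 1.27 and Sgk1 at 0.6. Cell cycle genes showed 2 higher and 13 lower of 31 (3 and 16 adjusted over the list alone; adjusted p = 0.0024, but adjusted p = 0.0839 with an estimated correlation), and 6 and 10 with an equal T cell identity median. The higher ones, named after their values were seen, were Mcm3 at 0.42 and Ccnd2 at 0.21. Th17 genes showed 4 higher of 8 (5 adjusted over the list alone; adjusted p = 0.0024, but adjusted p = 0.0981 with an estimated correlation). Glycolysis genes showed 1 higher and 10 lower of 17 (2 and 10 adjusted over the list alone; adjusted p = 0.0104, but adjusted p = 0.135 with an estimated correlation), and 2 and 6 after quantile normalization (adjusted p = 0.0866), with Hk2 higher by 1.39 ± 0.13. Cholesterol synthesis genes showed 10 higher and 3 lower of 22 (11 and 3 adjusted over the list alone; adjusted p = 0.0166, but adjusted p = 0.129 with an estimated correlation), the lower ones, named after their values were seen, being Pmvk, Fdps and Ebp at -0.67, -0.47 and -0.35. It was not called without WT db-cAMP replicate 2 (adjusted p = 0.0839) or KO db-cAMP replicate 2 (0.0614). The control spots and 3-prime to 5-prime ratios lay apart as under vehicle, and markers moved both ways beside these groups. Of 11 B cell markers 1 was higher and 2 lower, the same adjusted over the list alone (adjusted p = 0.465), namely Ighm at 0.64 ± 0.1, which stood at -0.39 (adjusted p = 0.264) as the mean of its probe sets, Cd79b at -1.28 ± 0.4 and Ms4a1 at -0.76 ± 0.25. The CD8 marker Cd8b1, 1 of 2, stood at -0.89 ± 0.21, the dendritic cell marker Cst3, 1 of 8, at -0.53 ± 0.09, and Lyz1, 1 of 9 macrophage and neutrophil markers and 0 adjusted over the list alone, at 1.03 ± 0.31 (adjusted p = 0.386, 0.219 and 0.918 for these lists). Of 12 T cell identity genes 5 were higher and 4 lower, the same adjusted over the list alone (adjusted p = 0.871), and 5 and 2 after quantile normalization. The T cell receptor chain Cd247 stood at -1.2 ± 0.07, against the receptor kinase Zap70 at 0.9 ± 0.08, Cd6 at 0.61 and Cd5 at 0.56 and, named after their values were seen, Cd28 at 0.34 and Cd3e at 0.27.

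Under db-cAMP 3529 genes passed, 1926 higher and 1603 lower in KO cells. With an equal 75th percentile, which put the median of all genes at -0.126, the split was 1375 higher and 2246 lower. With an equal T cell identity median, an alternative chosen after seeing the data that put this median at 0.166, it was 2925 and 894. Calls lost without the intensity trend were Cd79b (adjusted p = 0.0849), Ms4a1 (0.0647), Rel (0.106), Sgk1 (0.0914), Ccnd2 (0.14), Fdps (0.0576), Ebp (0.0901) and Fbl (0.0662), and with an equal T cell identity median Cd79b (0.0543), Ms4a1 (0.0943), Tnfrsf9 (0.0776), Rel (0.18), Ebp (0.181) and Fbl (0.0678). Sgk1 was lost after quantile normalization (0.0731) and with an equal 75th percentile (0.0691), as was Ccnd2 in the latter (0.392). Without a filter Cd79b (0.0604), Ms4a1 (0.0696) and Ccnd2 (0.0624) were lost, with only the db-cAMP arrays Cd79b (0.0513) and Ms4a1 (0.0516), and as the mean of probe sets Mcm3 (0.106) and Ncl (0.825). Those lost without WT db-cAMP replicate 1 were Cd79b (0.0651), Rel (0.143), Ccnd2 (0.124) and Ebp (0.0798), and without WT db-cAMP replicate 2 Cd79b (0.116), Ms4a1 (0.249) and Sgk1 (0.226). Without KO db-cAMP replicate 1 Ms4a1 (0.0933), Rel (0.0899) and Ccnd2 (0.155) were lost, and without KO db-cAMP replicate 2 Cd79b (0.304), Ms4a1 (0.164), Rel (0.117), Sgk1 (0.241), Ccnd2 (0.115) and Ebp (0.163). Cd3e was lost without the trend (0.142), without WT db-cAMP replicate 1 (0.161) or 2 (0.0618) or KO db-cAMP replicate 1 (0.135) or 2 (0.145), after quantile normalization (0.1), with an equal 75th percentile (0.246) and over every probe set (0.0512). Lyz1 was lost without WT db-cAMP replicate 1 (0.0798) or KO db-cAMP replicate 2 (0.223), without a filter (0.055) and as the mean of its probe sets (0.0577), and Cd28 without the trend (0.0559) and as the mean of its probe sets (0.35). With a filter at the 75th percentile the Th17 (0.0536) and cholesterol synthesis (0.0907) lists were not called. Counting every probe set gave 6431 calls.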

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

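The tests of a compressed range, of lost interferon induction alone, of a weaker exposure, of KO signals by their mean over the KO arrays and of the batch were chosen after the result was seen, and the others before.

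The genes listed here stood out because the effect of db-cAMP differed between WT and KO cells in the interaction test, which called 1425 genes. A negative value is a KO effect below the WT effect. Among interferon-related genes these were Igtp at -1.92, Cxcl10 at -1.93, Gbp6 at -1.66, Irgm1 at -1.56, Irf1 at -1.11, Ifit1 at -2.95 and Usp18 at -1.74, and for the receptor chains Ifngr1 at -1.62 and Ifngr2 at -1.29. Among cAMP targets and phosphodiesterases they were Fosl2 at -1.55, Crem at -1.46, Pde4d at -1.07, Pde4b at -1.03, Pde3b at -0.82, Nr4a2 at -0.46, Nr4a1 at 0.59, Rgs1 at 0.72 and Id3 at 1.04. Activation and growth genes were Il2 at 2.15, Egr3 at 1.99, Egr2 at 1.69, Myc at 1.46, Lta at 1.1, Rel at -0.66, Tnfrsf9 at -0.39, Gnl3 at 1.55, Polr1b at 1.38 and Hk2 at 1.46. Homing and quiescence genes were Cxcr4 at -1.78, Ccr7 at -0.9, Slfn2 at 1.13, Foxp1 at 0.81 and Bach2 at 0.74. The remaining ones were Hivep3 at 3.22, Ppargc1b at 2.91, Sardh at -4.09, Il12rb1 at 1.42, Fasl at -1.25, Socs3 at -1.2, Stat3 at -0.98 and Stat4 at -0.77.

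Some of these differences rested on 1 setting or array. Hivep3 stood at 0.74 (adjusted p = 0.238) and Stat3 at -0.54 (0.104) as the mean of their probe sets. Sardh was not called without KO vehicle replicate 1 (0.0697), Usp18 not without KO vehicle replicate 2 (0.0599) or KO db-cAMP replicate 1 (0.0597), and neither Il12rb1 (0.0524) nor Nr4a2 (0.0532) without KO db-cAMP replicate 1. Ifit1 was lost without WT vehicle replicate 2 (0.095), WT db-cAMP replicate 1 (0.107) or 2 (0.0913), KO vehicle replicate 2 (0.144) and KO db-cAMP replicate 1 (0.0929) or 2 (0.0854), without a filter (0.0601), without an offset (0.0698) and as the mean of its probe sets (0.0515). As the mean of their probe sets Nr4a2 stood at -0.42 (0.544) and Pde4b at -0.14 (0.905). Without the intensity trend the calls of Ifit1 (0.146), Usp18 (0.125), Irgm1 (0.0524), Pde4d (0.082), Pde4b (0.0719), Pde3b (0.0992), Nr4a2 (0.0966), Lta (0.0552), Polr1b (0.0763), Il12rb1 (0.0596), Socs3 (0.0669) and Stat3 (0.0694) were lost, besides those named with the interaction above.

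The same test, with the preset correlation, raised 6 gene lists. Their median interactions were -0.46 for cAMP and CREB targets, -0.76 for interferon-gamma induced genes, -0.62 for type I interferon induced genes, 0.56 for activation genes, -0.49 for quiescence and homing genes and 0.77 for ribosome biogenesis genes. With an estimated correlation the interferon-gamma induced and ribosome biogenesis lists stayed past the threshold (adjusted p = 0.0166 each) and the other 4 did not (adjusted p = 0.0922 each). Control probe sets, which the comparisons do not use, gave 3 further signals. Poly-A controls were brighter on KO than WT arrays by 1.53 on the log2 scale. The 18S rRNA probe sets were brighter after db-cAMP by 0.49 in WT and 0.46 in KO cells.

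The first pattern is that db-cAMP effects were smaller in KO cells. A compressed range of the KO arrays is argued against for the called genes as a whole. Vehicle levels of the 4032 called genes had a KO on WT slope of 0.973 (0.967 to 0.979 leaving out each array). A slope over all levels does not show compression limited to the brightest signals, which stays open. The highest signal of an array ran from 65165 to 72626 on KO and from 86708 to 131247 on WT arrays. Lost induction confined to the interferon lists and the genes that differed under vehicle is argued against as the only source. The slope of effects was 0.442 (0.428 to 0.46) over the 3317 called genes without them. Genes that need the receptor only under db-cAMP stayed among the 3317, and 3529 genes differed between genotypes there against 1311 under vehicle. A wider loss of interferon signalling as the only source therefore stays open. A weaker exposure of the KO cultures to db-cAMP stays open and may account for part of the pattern. The slope over 24 called cAMP and CREB targets was 0.616 (0.591 to 0.675). With a common slope of 0.438, a reduced slope there does not single out this cause. Against the common slope the 27 targets stood higher in KO cells (camera adjusted p = 0.00434, but adjusted p = 0.164 with an estimated correlation). List slopes were unequal, at 0.162 over 26 called ribosome biogenesis genes and 0.258 over 6 T cell identity genes. They were 0.299 over 12 cholesterol synthesis genes and 0.766 over 5 Th17 genes. They follow the spread of members about the list mean, not the size of the KO effect. Mean changes were 1.19 in WT and 0.76 in KO cells for the 27 targets, and -1.08 and -0.35 for 28 ribosome biogenesis genes. How each list responds to dose was not measured. An effect of receptor loss on the cAMP response also stays open, as the design does not part it from a weaker exposure.

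The second pattern is that interferon-gamma induced genes rose after db-cAMP in WT cells while Ifng fell. General shrinkage of effects in KO cells is argued against as the reason for their weaker KO response. Against the common slope the 30 members stood lower in KO cells (camera p = 0.00235 with an estimated correlation, 1.5e-09 with the preset one). Over all 25 lists, however, the adjusted p with an estimated correlation was 0.0588. Their mean log2 change was 0.78 in WT and 0.05 in KO cells. The slope over their 23 called members was 0.663, which follows the spread of members about the list mean and not the size of the KO effect. It lies above the common 0.438. KO signals too low to show a rise are argued against by 18 members bright by their mean over the KO arrays, which stood lower than that slope gives (camera p = 0.00426 with an estimated correlation, 6.46e-08 with the preset one), whereas the median of -0.22 over 18 members bright under KO vehicle (exact two-sided sign test p = 0.000145) is weaker evidence, as that test takes genes of the same arrays as independent and their vehicle signal enters the effect. A hypothesis is that the WT rise may pass through the IFN-γ receptor, since the list did not pass in cells without it (adjusted p = 0.57). There 17 of the 30 members had a lower effect (interaction adjusted p = 2.51e-11, and adjusted p = 0.0166 with an estimated correlation). This interaction does not single out the receptor, as cAMP and CREB targets (median -0.46) and quiescence genes (-0.49) also had lower effects. With the WT effect scaled, the members called were Igtp, Cd274 and Irf8. Of these Igtp rose in WT cells (2.08), Cd274 fell (-0.32) and Irf8 did not pass (0.17, adjusted p = 0.193). Whether the rise of Ifngr1 and Ifngr2 in WT cells has a part in the rise of the list was not tested.

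The third pattern is the difference between KO and WT cells at equal treatment. Poly-A controls, added before labelling, were 2.89-fold brighter on the KO arrays, with no overlap between genotypes. Each genotype lay on its own side, so in general a labelling or hybridization batch and the genotype cannot be told apart for these comparisons. Of 30 interferon-gamma induced genes, however, 25 were lower and 0 higher in KO cells under vehicle, and 28 and 0 under db-cAMP. Their median was -1.67 under vehicle, against -0.005 over all genes. Such a batch has no known tie to what induces a gene, so these values argue against it as the sole cause for this list. The IFN-γ receptor genotype stays among the open explanations.

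The 8 arrays were split into 4 and 4 in all 35 ways. The fit took the 2 sides as groups and, except for KO against WT, held a genotype term. It called 3024 genes for db-cAMP against vehicle. In 1 of the 35 splits, the real one, were so many genes called. KO against WT came next with 704, and the highest split other than these called 0. In splits that mix the treatments the db-cAMP effect adds to the spread and lowers the calls. With 35 splits the count is also coarse, so it cannot by itself exclude chance for the db-cAMP effect over both genotypes.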

How the results depend on the processing

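The scaling of the WT effect and the equal T cell identity median were chosen after seeing the data, and the other alternatives before. Over 20 alternatives, directions and calls of named genes were mostly kept, and where they were not, the cause was not tested. Of 6310 values of named genes 5879 kept direction and side of the threshold, 394 fell short of it, 95 of them without the intensity trend and 39 as the mean of probe sets, 12 newly passed and 25 turned. Of 831 values of called list tests 797 stayed past the threshold and 34 did not. All of these list tests used the preset correlation, so this tally leaves out the change to an estimated correlation. With the latter many of the called lists did not pass, as given with each comparison above. Without the intensity trend 188 genes passed in KO cells, 251 for KO against WT under vehicle and 261 for the interaction. Every probe set, which counts a gene more than once, gave 6890, 6575, 2733 and 6431 calls in WT, for the mean, and for KO against WT under vehicle and db-cAMP. The mean of probe sets gave 598 in KO cells and 848 for the interaction, and the scaled WT effect left 30. Leaving out each array gave 446 to 1089 calls in KO cells, 617 to 1391 for KO against WT under vehicle and 891 to 1336 for the interaction. The slope of KO on WT effects stayed between 0.384 and 0.484. The correlation of both effects over all genes was 0.328 without an offset, 0.619 with an offset at the median, 0.194 without a filter, 0.815 with a filter at the 75th percentile, 0.316 over every probe set, 0.368 for the mean of probe sets and 0.327 to 0.378 leaving out each array.

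Directions that turned are these. Quantile normalization put Npm1 at 0.01 under vehicle and Ncl at 0.06 and Fbl at 0.01 under db-cAMP for KO against WT. An equal 75th percentile put Il17a at 0 in KO cells. The mean of probe sets put Bcl2l11 at 0.08 and Supt16 at 0.07 in WT cells, Pde4b at -0.07 for KO against WT under vehicle, and Ighm at -0.39 and Nr4a2 at 0.43 under db-cAMP. An equal T cell identity median put Il12rb1 at 0.07 and Nr4a2 at 0.1 there. Leaving out each array gave ranges across 0 for Nr4a1 (-0.09 to 0.23) and Il17a (-0.01 to 0.2) in WT cells. In KO cells these were Il12rb1 (-0.07 to 0.01), Il12rb2 (-0.09 to 2.32), Irf1 (-0.03 to 0.32), Il17a (-0.09 to 0.18) and Igtp (-0.01 to 0.34). They were also found for Il12rb1 under db-cAMP (-0.35 to 0.15) and for the interaction of Il12rb2 (-2.21 to 0.21) and Il17a (-0.18 to 0.09).

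With the replicate number as a block, 4184 genes were called in WT, 935 in KO, 4024 for the mean, 1250 and 3485 for KO against WT under vehicle and db-cAMP and 1373 for the interaction, and the correlation stayed at 0.396. Deviations of same-numbered arrays correlated at -0.02 to 0.021, so no common deviation was seen. Whether same-numbered arrays shared a mouse, culture or preparation cannot be told from this. The block ended the calls of Slfn2 at -0.27 (adjusted p = 0.0509) and Insl6 at -0.78 (0.0596) in KO cells and of Stat4 at -0.26 (0.0562) for KO against WT under vehicle, and changed no other call of a named gene or list. These calls were lost in other settings too. Insl6 was lost with an offset at the median (0.0676), without a filter (0.0927) and without the intensity trend (0.156). Stat4 was lost without a filter (0.0586) and without the trend (0.176).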

Other observations

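The tests of gene families and the scaled comparison of the genotypes were chosen after the result was seen, and the test of the genes near Ifngr1 before.

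Of 10 measured genes taken as phosphodiesterases by their Pde names, 6 rose and 1 fell with db-cAMP in WT cells. Not all of them need break down cyclic nucleotides. The family did not pass (camera adjusted p = 0.051 over 5 families, and adjusted p = 0.34 with an estimated correlation). Among them were Pde8a at 1.79 ± 0.22 and Pde7a at 0.65 ± 0.14, while Pde6d stood at -0.81 ± 0.14, and the genes of these families named here were chosen after their values were seen. In KO cells 4 rose and 0 fell (adjusted p = 0.00648, but adjusted p = 0.215 with an estimated correlation). Dual-specificity phosphatases, taken by their Dusp names and only some of which switch off MAP kinases, moved both ways in WT cells, with 5 rises and 4 falls among 16 (adjusted p = 0.577). Dusp10 stood at 3.01 ± 0.11 and Dusp1 at 1.67 ± 0.1, against Dusp6 at -2.37 ± 0.1. RGS proteins, which shorten G protein signals, showed 2 rises and 4 falls among 12 (adjusted p = 0.577), with Rgs2 at 2.13 ± 0.07 and Rgs16 at -1.78 ± 0.16. Chemokine receptors showed 3 rises and 0 falls among 14 in WT cells (adjusted p = 0.051), and 2 and 0 in KO cells (adjusted p = 0.218). TNF superfamily ligands showed 2 rises and 5 falls among 12 in WT cells (adjusted p = 0.435), and 1 and 5 in KO cells (adjusted p = 0.00909, but adjusted p = 0.225 with an estimated correlation).

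When the WT effect was scaled down by the common slope of 0.438, the interaction called 30 genes, 9 with a lower and 21 with a higher KO effect than that slope gives. The lower ones included Cd274 at -1.13, Irf8 at -0.92, Igtp at -0.75, Ifi47 at -0.64 and Fasl at -0.53. The higher ones included Rora at 1.26, Ramp3 at 1.23, Pde4d at 1.03, Cblb, a ubiquitin ligase that restrains T cell activation, at 0.67 and Stat4 at 0.62. These examples were named after their values were seen, as were the next ones. Called in opposite directions in the genotypes were 7 genes, among them Ifi47, an interferon-induced GTPase, at 0.69 in WT and -0.33 in KO cells (interaction adjusted p = 3.14e-05) and Bcl2l11, which encodes the pro-apoptotic BIM, at -0.26 and 0.46 (0.00168). Without the intensity trend all 7 lost their KO call (adjusted p from 0.119 to 0.212). The KO call of Ifi47 was lost without KO vehicle replicate 1 (adjusted p = 0.0596), KO db-cAMP replicate 1 (0.133) and the intensity trend (0.151). That of Bcl2l11 was lost in KO cells without KO db-cAMP replicate 2 (0.0751) and the trend (0.119). In WT cells Bcl2l11 was lost without WT vehicle replicate 2 (0.229), WT db-cAMP replicate 1 (0.102) or 2 (0.0854), the trend (0.138), after quantile normalization (0.0598) and with only the 4 WT arrays (0.0513), and it stood at 0.08 as the mean of its probe sets.

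Genes near Ifngr1 on its chromosome were called more often for KO against WT. Of 39 measured genes among the 100 nearest annotated ones on each side, 7 (17.9%) were called in both treatments, against 824 of 12051 others (6.84%; Fisher's exact two-sided p = 0.0157). They were Adat2, Aig1, Hivep2, Map7, Sf3b5, Stx11 and Tbpl1, named after their values were seen. A candidate explanation is flanking DNA of another strain carried along with the targeted gene. Neighbouring genes are not independent, and the strain of the mice was not tested.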
